A study of Homo sapiens with 6 samples.

How the data were processed

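RNA was measured in 22RV1 cells, an established human cell line of castration-resistant prostate cancer that grows without androgen. The 6 libraries fall into 3 groups of 2, all from day 2 per the labels: a control called NC, cells overexpressing the long noncoding RNA MAGI2-AS3 (OE), and cells given miR-106a-5p, called mimics in the sample titles. The treatment text in the labels speaks of overexpression plasmids for the noncoding RNA or the microRNA, so the form in which the microRNA was delivered is uncertain, and the nature of NC is not described. Nothing in the labels says that replicates are separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

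Total RNA was extracted with TRIzol and libraries were made with a Hieff NGS Ultima Dual-mode mRNA kit, per the labels' protocols. HISAT2 2.0.4 and the build GRCh38 are named in the submitters' processing notes. The counting tool, its annotation and its use of strand are not given in the sources used here. The values deposited by the authors are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), with 1 column per library in a table of 24872 rows. An Ensembl gene ID was given for 19974 rows, all found in GENCODE 29, of which 19922 were protein-coding and 52 of other kinds, and 4898 rows were named as new genes. Because FPKM divides by each library's total, a large change in a few abundant transcripts shifts all other values of that library. Gene length is divided out, so low FPKM of a short gene rests on fewer fragments than the same FPKM of a long one.

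FPKM holds no read counts, and counts were not recovered. A repeated step in FPKM times length in kb among 940 single-exon genes, searched only between 0.03 and 0.08, was taken as 1 fragment. It gave an approximate depth of 20800000 and 22400000 fragments for the NC libraries, 15900000 and 21100000 for OE and 21400000 and 17300000 for mimics. These figures rest on 8 to 16 genes per library within a tolerance of 0.3%. Values at a smaller step also recurred, in 3 to 12 genes per library. In mimics replicate 2 these were 11 genes, against 9 at the step used. The depth may thus be higher than given, and the search window limits what could be found. Counting error per gene was therefore not computed, and precision is given by the spread between replicates.

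Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), over rows with a mean of at least 0.5 FPKM, with an intensity trend in the empirical Bayes step. All 6 libraries entered a single model, so that the 3 groups shared one estimate of the spread with 3 residual degrees of freedom and 5.67 prior degrees of freedom. This takes the spread to be equal in the 3 groups, although the mimics libraries differed more from each other than those of NC or OE. Tests were two-sided and adjusted by Benjamini-Hochberg over 13998 rows (12360 annotated and 1638 new genes), with a threshold of 0.05. Every fold change is on the log2(FPKM + 0.5) scale, which understates the change of genes with low FPKM. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so limma is the only test of single genes used. Values are means ± SD of FPKM with n = 2 per group.

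The comparisons, the test, the rule for named genes, 25 gene lists and the alternative settings were chosen before the data were examined. The rule named, for each comparison with NC, up to 12 genes with the largest rise and 12 with the largest fall among annotated genes that passed and whose libraries did not overlap, and filled up to 10 with the next genes by unadjusted p, given as not passing. It also named RAB31 and MAGI2, up to 3 passing members of each list (or 2 members if none passed), the 6 genes with the largest difference in each direction between OE and mimics, and genes called in opposite directions. The lists covered androgen response, mitosis, DNA replication, mesenchymal and migration genes, epithelial genes, RAB GTPases, interferon response, NF-kB and inflammation, p53 targets, endoplasmic reticulum (ER) stress and amino acid genes, hypoxia and glycolysis, cholesterol and lipid synthesis, neuroendocrine genes, ribosomal proteins, nuclear oxidative phosphorylation genes, immediate early genes, known targets of the miR-17 family, microRNA machinery and hosts, the MAGI2 locus, markers of fibroblasts, leukocytes, endothelium and basal prostate cells, and mitochondrially encoded and histone genes as signs of RNA quality. Of 498 listed symbols, 7 were not analysed here under that name, and 21 lists held at least 3 measured members. Among the 7 were ATP5A1 and ATP5B, older names of ATP5F1A and ATP5F1B, which were analysed. Values of some genes that the rule named are not reported here.

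Each list was tested with fry, which asks whether its genes move one way on balance and does not compare them with other genes, and with camera, which does compare them, with a preset correlation between genes of 0.01 and again with an estimated correlation. Adjustment was over the 21 lists of a comparison. Members were counted by their adjusted p over all rows and also adjusted over the list alone.

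For miR-106a-5p, the longest annotated 3′ UTR of each of 19119 genes (GENCODE 29, GRCh38) was searched for GCACTTT, the match to microRNA positions 2 to 8. The median fold change of genes with a match was set against 10000 random gene lists matched on expression and 3′ UTR length. Agreement between the OE and mimics responses, which share the NC libraries, was set against 100 simulations of unchanged groups with shared controls and against the overlap of independent lists. After the data were seen, the fold changes were also taken with 1 NC library for each comparison. Coordinates are 1-based on GRCh38.

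The fitting code was tested on simulated data over 13998 genes with 50 genes changed at each size. At a log2 change of 1, 94% of changed genes were recovered for OE against NC, 86% for mimics against NC and 86% for OE against mimics with the estimated gene spreads, and 66%, 72% and 74% with spreads drawn from the fitted prior. At a log2 change of 0.5 these shares were 26%, 32% and 12%, and 10%, 12% and 2%. Changes of that size were thus mostly missed. False calls made up 3.52% to 11.3% of all calls over these 6 runs. Other settings tried were pseudocounts of 1 and 0.1, no filter and a filter of 2 FPKM, quantile normalization, rescaling to an equal sum, median centring, empirical Bayes without a trend and in robust form, only the libraries compared, the replicate number as a block, an adjusted p threshold of 0.1, and leaving out each library. Rescaling without mitochondrially encoded genes, annotated genes only and leaving out genes that share exon sequence were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used for the remaining steps.

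Genes that share exons or lie antisense to another gene are named as such, since reads of such pairs may have been assigned to either. Of annotated tested genes, 32.7% overlap another gene, against 28.6%, 30.1% and 28.4% of those called in OE against NC, mimics against NC and OE against mimics.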

Results

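Gene expression was profiled by RNA sequencing in 22RV1 prostate cancer cells, in 2 control (NC), 2 MAGI2-AS3-overexpressing (OE) and 2 miR-106a-5p (mimics) libraries. The series title places this noncoding RNA, this microRNA and the GTPase RAB31 in a single axis that restrains growth and migration. The 6 libraries held 402526 to 429262 FPKM in sum, with 12344 to 12983 rows at 1 FPKM or more, and an approximate depth of 15900000 to 22400000 fragments. Across tested rows, which are not independent replicates, the 2 libraries of a group correlated at r = 0.992 for NC, 0.994 for OE and 0.983 for mimics. Libraries of NC correlated with those of OE almost as closely, at 0.988 to 0.991. The first principal component held 50.2% of the variance and set the mimics libraries (24.98 and 32.6) apart from NC and OE (-16.3 to -12.2). The second held 20.1% and split mimics replicate 1 (-19.8) from mimics replicate 2 (23.7).

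The mimics libraries also differed in RNA composition. The 13 mitochondrially encoded genes took 6.23% of the FPKM sum in mimics replicate 1 and 0.533% in mimics replicate 2, against 8.29% to 9.67% in NC and OE. Ribosomal protein genes took 19.8% and 17.5% in the mimics libraries, against 12.7% and 13.5% in NC and 13.9% and 14.9% in OE. Rescaling the libraries without the mitochondrially encoded genes moved the median change of all tested rows in mimics against NC to -0.09.

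**Figure D1:**
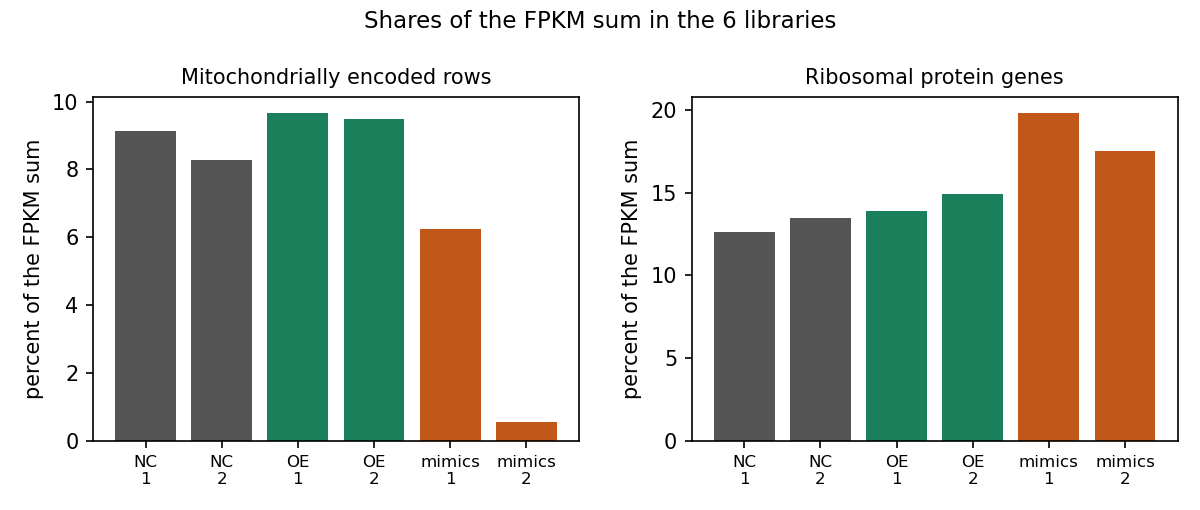
Percentage of each library's FPKM sum taken by mitochondrially encoded genes and by ribosomal protein genes, 1 bar per library, for NC, OE and mimics. The mitochondrial share was 0.533% in mimics replicate 2 and 6.23% in mimics replicate 1, and at least 8.29% in the NC and OE libraries.

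RAB31, a small GTPase of endosomal and Golgi traffic named in the series title, was 1.72 ± 0.176 FPKM in NC, 0.983 ± 0.00442 in OE and 5.00 ± 0.255 in mimics (SD, n = 2 each). It rose in mimics against NC by a log2 change of 1.31 (95% confidence interval 0.95 to 1.67, adjusted p = 0.00356) and was lower in OE than in mimics by -1.89 (-2.25 to -1.53, adjusted p = 0.000619). The difference between OE and NC, -0.58 (-0.94 to -0.22), did not pass by limma (unadjusted 0.00539, adjusted p = 0.413, 0.140 to 0.9999 over the other settings), although both OE libraries lay under both NC libraries. RAB31 (ENSG00000168461) lies on chromosome 18 from 9708165 to 9862551 on the plus strand of GRCh38. Its 3′ UTR of 3226 nucleotides holds 1 match to the miR-106a-5p seed, GCACTTTA, with the 7-nucleotide core at 9860324 to 9860330 (position 999 of the 3′ UTR) in the context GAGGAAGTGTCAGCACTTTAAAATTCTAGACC.

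MAGI2-AS3 itself, annotated on chromosome 7 from 79452877 to 79471208 on the plus strand, was not analysed here, so its overexpression was not checked against the labels. MAGI2, which encodes a membrane scaffold protein and overlaps the start of MAGI2-AS3 on the opposite strand (chromosome 7, 78017057 to 79453574), was 0.730 ± 0.169 FPKM in NC, 0.602 ± 0.0211 in OE and 1.12 ± 0.00211 in mimics. None of its differences passed (adjusted p = 0.998 for OE against NC, 0.220 for mimics against NC and 0.106 for OE against mimics). MAGI2 was the only measured member of the MAGI2 locus list.

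**Figure D2:**
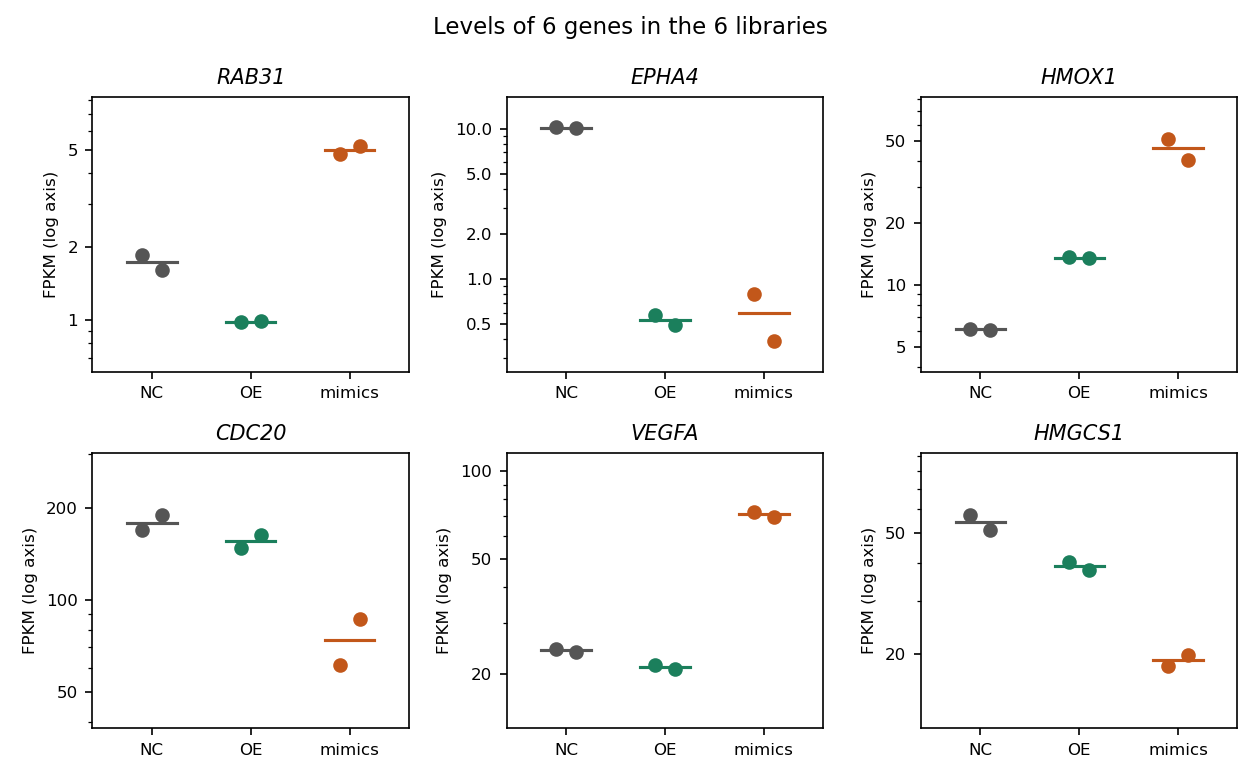
FPKM of RAB31, EPHA4, HMOX1, CDC20, VEGFA and HMGCS1 on a log axis, with 1 point per library and a bar at the mean of each group of 2. RAB31 averaged 1.72 in NC, 0.983 in OE and 5.00 in mimics, and EPHA4 10.2, 0.539 and 0.594.

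The comparison of OE with NC asked which genes changed with MAGI2-AS3 overexpression. A small set of genes was lower in OE than in NC, and few were higher. Of the 34 called lower, 19 were also called lower in mimics. A loss in OE cells therefore cannot be told apart from a higher level in the NC cells. EPHA4 (ENSG00000116106), an ephrin receptor tyrosine kinase, fell from 10.2 ± 0.110 to 0.539 ± 0.0570 FPKM (SD, n = 2, log2 change -3.37, SE 0.21, adjusted p = 0.00113). GJA3, a connexin of gap junctions, fell from 4.30 ± 0.0915 to 0.172 ± 0.00402 FPKM (-2.84, adjusted p = 0.00113), and RGMA, a repulsive guidance molecule, from 3.08 ± 0.202 to 0.126 ± 0.106 (-2.52, adjusted p = 0.00460). HMOX1 (ENSG00000100292), the stress-induced enzyme that breaks down heme, rose from 6.11 ± 0.0422 to 13.6 ± 0.0291 FPKM (1.09, SE 0.13, adjusted p = 0.0129).

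Other falls in OE included MAOA, a mitochondrial enzyme that oxidises monoamines, from 14.6 ± 0.245 to 3.31 ± 0.382 FPKM (-1.99, adjusted p = 0.00460), and S100A6, a calcium-binding protein, from 9.22 ± 0.807 to 2.61 ± 0.315 (-1.64, adjusted p = 0.00460). SPOCK2, a matrix proteoglycan, fell by 2.13 on the log2 scale (adjusted p = 0.0129). DKK1, a secreted WNT antagonist, fell by 1.86 (adjusted p = 0.0129), ANXA2, a membrane-binding annexin, by 1.68 (adjusted p = 0.0165) and AKR1C2, a steroid-reducing enzyme, by 1.46 (adjusted p = 0.0150). Read assignment was uncertain for Z83844.3, which rose by 1.42 (adjusted p = 0.0364) and shares exons with PDXP and SH3BP1, and for AC235565.2 (-2.25), which shares exons with NXF2B and TCP11X2. It was also uncertain for CRYAB (-1.87), antisense to HSPB2, and for STAT6 (-1.70), antisense to LRP1 and NAB2. The next genes in the direction of a rise did not pass: CACNA2D1 (0.81, adjusted p = 0.0905), TFRC (0.57, 0.116), PCDHA4 (0.94, 0.181, exons shared within the protocadherin cluster), KRT7 (1.23, 0.204), TRIM16L (0.65, 0.214), AC005154.5 (0.88, 0.226, exons shared with GGCT), TXNRD1 (0.45, 0.264) and NMB (0.48, 0.264).

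In all, 36 of 13998 rows passed in OE against NC, 2 higher and 34 lower, 1 of them a new gene. At an unadjusted p under 0.05 there were 907 rows, and 29 calls exceeded a change of 1 on the log2 scale. OE and NC libraries did not overlap for any of the 36, nor for 41.9% of all tested rows against 33.3% by chance. The count was lower without any 1 of the 4 NC and OE libraries. It was higher without either mimics library, when the spread was estimated from NC and OE alone. Leaving out an NC or OE library leaves 1 library in a compared group and fewer residual degrees of freedom. The lower counts therefore do not show that a particular library carried the calls. Without a filter on expression limma called 0 rows (1334 at an unadjusted p under 0.05), and with only the 4 libraries compared 119. Of the 17 named genes that passed, 2, 2, 7 and 5 still passed without NC replicate 1, NC replicate 2, OE replicate 1 and OE replicate 2, and all 17 without mimics replicate 1 or 2.

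None of the 21 testable lists passed fry's test for change in 1 direction in OE against NC (0 of 21, with 5 at an unadjusted p under 0.05). In its test for change in either direction 6 passed, namely miR-17 family targets (adjusted p = 0.000217), mesenchymal genes (0.00632), epithelial genes (0.0223), and hypoxia, interferon and RAB genes (0.0465 each). Camera called 14 with the preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05). Epithelial genes came nearest, with a median log2 change of -0.21 and none of 17 members past the threshold, such as CLDN3 (-0.70) and CLDN7 (-0.50), and 2 lower when adjusted over the list alone (adjusted p = 0.0635, and 0.308 with an estimated correlation). After quantile normalization this list passed at 0.0127, and over all settings its adjusted p was 0.0127 to 0.260. Mesenchymal and migration genes had a median of -0.13, and S100A4, a calcium-binding protein of motile cells, was the only one of 15 members to pass, falling from 2.56 ± 0.519 to 0.710 ± 0.178 FPKM (log2 change -1.34, adjusted p = 0.0356). The list itself had adjusted p = 0.0706, and 0.308 with an estimated correlation, but 0.0214 with a filter of 2 FPKM (0.0214 to 0.423 over all settings).

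Of 49 known targets of the miR-17 family, which share the miR-106a-5p seed, EPHA4 and F3 fell, and 7 were lower when adjusted over the list alone (median -0.10, adjusted p = 0.124). F3, tissue factor, went from 38.98 ± 0.159 to 21.1 ± 0.168 FPKM (-0.87, adjusted p = 0.0129). Cholesterol and lipid synthesis genes had a median of -0.38 with 0 of 23 members passing over all rows (limma) and 8 lower when adjusted over the list alone, and the members with the largest changes were SCD (-1.06) and SQLE (-0.70). That list had adjusted p = 0.160 by fry, 1.57e-13 by camera with the preset correlation and 0.308 with an estimated correlation. In both OE libraries 22 of the 23 members lay under both NC libraries, against 33.3% by chance for a single gene. The scatter of the members was correlated (estimated correlation 0.332), so they are not independent replicates. Hypoxia and glycolysis genes had a median of -0.24, and PFKFB4, a regulator of glycolysis that overlaps UCN2, fell from 5.82 ± 0.282 to 2.84 ± 0.118 FPKM (-0.92, adjusted p = 0.0213) as the only one of 20 to pass (list adjusted p = 0.160).

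In the remaining lists no member passed. Medians and adjusted p were -0.15 and 0.280 for androgen response (TMPRSS2 -0.78, NDRG1 -0.70), -0.24 and 0.274 for immediate early genes (EGR3 -1.08, FOS -0.66), -0.20 and 0.146 for interferon response (IFI6 -0.80, ISG20 -0.55), and -0.18 and 0.160 for NF-kB and inflammation (RELB -0.46, TNFAIP2 -0.44). They were -0.12 and 0.489 for mitosis (AURKB -0.36, KIF20A -0.32) and 0.05 and 0.953 for DNA replication (CCNE1 0.28, CHAF1B 0.24). They were 0.11 and 0.160 for p53 targets (TP53I3 -0.35, GDF15 0.31), 0.16 and 0.489 for ribosomal proteins (RPS23 0.52, RPL37A 0.31), and 0.08 and 0.382 for nuclear oxidative phosphorylation genes (ATP5F1A 0.68, COX7B 0.21). ER stress and amino acid genes had a median of 0.01 and a mean of 0.01, whereas fry pointed down (adjusted p = 0.995; DDIT4 -0.67, SLC7A11 0.61). The RAB GTPases had a median of -0.01 while camera pointed up (adjusted p = 0.629; RAB31 -0.58, RAB5B -0.27). For microRNA machinery the median was -0.01 and the mean 0.00465 (adjusted p = 0.995; DICER1 0.25, AGO4 -0.20). Neuroendocrine genes had a median of 0.17 (adjusted p = 0.629; ENO2 -1.10, SCG3 0.36), fibroblast markers -0.08 (0.872; COL1A1 -0.36, COL3A1 0.19), histone genes 0.20 (0.953; HIST1H2BD -0.50, HIST1H2AC 0.27) and mitochondrially encoded genes 0.15 (0.995; MT-ATP6 0.29, MT-ND5 0.19). Of the genes named here, CLDN7, CHAF1B and MT-ATP6 overlap another gene on the same strand, and KIF20A, ATP5F1A, TP53I3 and RPS23 lie antisense to another, so that their values are uncertain to that extent.

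The comparison of mimics with NC asked which genes changed when miR-106a-5p was raised. In mimics all 22 mitosis genes and 13 of 23 cholesterol synthesis genes were lower, and 15 of 20 hypoxia and glycolysis genes, 8 of 22 p53 targets and 5 of 15 mesenchymal genes were higher. These 5 lists passed fry, but none passed camera with an estimated correlation (adjusted p = 0.146 for p53 targets and 0.246 for each of the others). That form of camera called 0 lists in every comparison. Mitosis, with all 22 members called, had an unadjusted p of 0.0457 in it, so its failures are weak evidence against a list. CDC20, an activator of the anaphase-promoting complex, fell from 179 ± 14.0 to 73.8 ± 17.8 FPKM (SD, n = 2, log2 change -1.29, SE 0.16, adjusted p = 0.00393). VEGFA, a hypoxia-induced growth factor for blood vessels, rose from 24.2 ± 0.451 to 71.1 ± 1.87 FPKM (1.54, SE 0.09, adjusted p = 0.000206), and CDKN1A, the p53-induced cell cycle inhibitor p21, from 64.2 ± 6.003 to 227 ± 49.7 (1.80, SE 0.15, adjusted p = 0.000854). HMGCS1, an early enzyme of cholesterol synthesis, fell from 54.3 ± 4.40 to 19.1 ± 1.11 FPKM (-1.48, SE 0.11, adjusted p = 0.000422).

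The largest rises with a computable fold were in PDK4, a kinase that slows pyruvate oxidation, from 12.8 ± 1.61 to 116.03 ± 48.2 FPKM (3.08, adjusted p = 0.000530), ADM, the vasodilator peptide adrenomedullin, from 1.11 ± 0.329 to 11.3 ± 3.18 (2.86, adjusted p = 0.000530), and HMOX1, from 6.11 ± 0.0422 to 46.0 ± 7.58 (2.80, adjusted p = 4.82e-05). The metal-binding metallothioneins MT1G (2.34, adjusted p = 0.00132) and MT1X (2.23, adjusted p = 0.000206) rose, as did GPNMB, a glycoprotein of lysosomes and melanosomes (2.31, adjusted p = 0.00141), the transcription factor BHLHE40 (2.13, adjusted p = 0.00420) and NRN1, neuritin (2.09, adjusted p = 0.00507). CRISP3, a secreted protein of the prostate, rose by 2.19 (adjusted p = 0.0251) with 9.60 and 2.42 FPKM in the mimics libraries. GDF15, a stress cytokine, went from 51.1 ± 4.19 to 209 ± 1.06 FPKM (2.02, adjusted p = 0.000166). Assignment is uncertain for the readthrough transcripts JMJD7-PLA2G4B (2.28, adjusted p = 0.0277) and ATP6V1G2-DDX39B, which was listed at 0 in both NC libraries, at 0 and 0.0239 FPKM in OE and at 8.65 and 9.04 in mimics.

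Falls in mimics were led by EPHA4 (-3.32, adjusted p = 0.000206), RGMA (-2.52, adjusted p = 0.000811) and GJA3 (-2.48, adjusted p = 0.000505), the genes that also led the falls in OE. SPOCK2 fell by 2.07 (adjusted p = 0.00356), DKK1 by 1.89 (adjusted p = 0.00223), EGR3, an immediate early transcription factor, by 1.70 (adjusted p = 0.0195), ANXA2 by 1.66 (adjusted p = 0.00400) and SLC43A3, a purine base transporter that overlaps AP000781.2, by 1.65 (adjusted p = 0.00488). STAT6, antisense to LRP1 and NAB2, fell by 1.62 (adjusted p = 0.00420). Uncertain by shared exons were ENSG00000015479, one of 2 rows for MATR3 (-2.27, adjusted p = 0.00873), AC118553.2 (-2.22, adjusted p = 0.00894) and AL445685.3 (-1.91, adjusted p = 0.0151).

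All 22 mitosis genes fell, including PLK1, a mitotic kinase whose locus is antisense to ERN2, from 70.7 ± 4.23 to 29.5 ± 4.98 FPKM (-1.255, adjusted p = 0.00209) and the proliferation marker MKI67 from 35.6 ± 4.83 to 14.8 ± 2.30 (-1.24, adjusted p = 0.00278). The list had a median log2 change of -0.94 (adjusted p = 0.0149, and 0.246 with an estimated correlation). Its median against the NC mean was -1.11 in mimics replicate 1 and -0.80 in mimics replicate 2, the library with few mitochondrially encoded reads. Under the 5 scalings 21 or 22 members fell. Of 25 DNA replication genes 6 fell, and 17 were lower when adjusted over the list alone, with a median of -0.47, but the list did not pass (adjusted p = 0.146, and 0.477 with an estimated correlation) except without mimics replicate 2 (0.0170, in a range of 0.0170 to 0.412). Examples were TYMS, thymidylate synthase, antisense to ENOSF1 (-0.74, adjusted p = 0.0146), the cyclin CCNE2, antisense to INTS8 (-0.72, 0.0186), and the origin licensing factor CDC6 (-0.71, 0.0262).

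Hypoxia and glycolysis genes rose: 15 of 20 passed, and 16 higher and 1 lower when adjusted over the list alone, with a median of 0.91 (adjusted p = 0.0102, and 0.246 with an estimated correlation). Beside ADM and VEGFA, PFKFB4 rose from 5.82 ± 0.282 to 23.3 ± 0.809 FPKM (1.92, adjusted p = 0.000206). GAPDH, a member that did not pass, was 2023 and 2341 FPKM in NC but 528 and 1717 in mimics. Of the 20 members 18 in mimics replicate 1 and 19 in mimics replicate 2 lay above both NC libraries, against 33.3% by chance for a single gene. The scatter of the members was correlated (estimated correlation 0.343), so they are not independent replicates. Under the 5 scalings 14 or 15 rose.

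Among 22 p53 targets 8 rose and none fell, 10 higher when adjusted over the list alone (median 0.36, adjusted p = 0.000805, and 0.146 with an estimated correlation). They were led by GDF15, CDKN1A and TP53INP1, a p53-induced stress protein (6.67 ± 0.264 to 18.2 ± 5.00 FPKM, 1.36, adjusted p = 0.00503). Of 23 cholesterol and lipid synthesis genes 13 fell, 18 when adjusted over the list alone (median -0.82, adjusted p = 0.0408, and 0.246 with an estimated correlation). Beside HMGCS1, SCD, the desaturase that makes monounsaturated fatty acids, went from 118 ± 5.97 to 49.97 ± 21.4 FPKM (-1.30, adjusted p = 0.0147) and SQLE, squalene epoxidase, fell by 1.25 (adjusted p = 0.0102).

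Mesenchymal and migration genes went both ways, with 5 of 15 higher and 1 lower, or 6 and 1 when adjusted over the list alone (median 0.32, adjusted p = 0.0112, and 0.246 with an estimated correlation). The risen members were ACTA2, smooth muscle actin, antisense to FAS (1.21, adjusted p = 0.0150), ITGA5, the fibronectin receptor subunit (1.13, 0.00430), LOX, a collagen crosslinking enzyme, antisense to SRFBP1 (1.05, 0.0155), the actin-binding TAGLN, antisense to PCSK7 (0.71, 0.0188) and the transcription factor SNAI2 (0.51, 0.0244). CTGF, a matricellular growth factor, fell by 0.88 (adjusted p = 0.0371). The 4 measured fibroblast markers had a median of 0.68 in the same libraries (adjusted p = 0.0881). None of them was higher over all rows by limma, and 4 were when adjusted over the list alone. LUM was 85.99 and 82.1 FPKM in NC and 172 and 103 in mimics. Epithelial genes had 2 higher, KRT19 (0.62, adjusted p = 0.0247) and GRHL2 (0.48, 0.0203), and 1 lower, the protease ST14 (-0.43, 0.0406), of 17, with 3 higher and 4 lower when adjusted over the list alone, and the list did not pass (median -0.02, adjusted p = 0.433).

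These 5 list calls changed when 1 library was left out, also an OE library, which enters this comparison only through the estimate of the spread. Losses may thus come from fewer degrees of freedom and do not mark a particular library. Mitosis and cholesterol synthesis no longer passed without NC replicate 1 (adjusted p = 0.123 and 0.200) or NC replicate 2 (0.103 and 0.236), and without OE replicate 1 or OE replicate 2 only the p53 targets passed (0.0193 each), with mitosis at 0.0914 and hypoxia and mesenchymal genes at 0.0644 and 0.0645. Cholesterol synthesis had 0.175 and 0.174 without OE replicate 1 and OE replicate 2. Without mimics replicate 1 there were 9 list calls and without mimics replicate 2 there were 8, and each of the 5 passed in both. After quantile normalization the cholesterol and mesenchymal lists had 0.0519 each. Over all settings the adjusted p was 0.00438 to 0.124 for mitosis, 0.00732 to 0.236 for cholesterol synthesis, 0.00619 to 0.0645 for hypoxia, 0.00128 to 0.0645 for mesenchymal genes and 0.000805 to 0.0307 for p53 targets. Camera called 10 lists with the preset correlation and 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 8 at an unadjusted p under 0.05. In fry's test for change in either direction 16 of the 21 lists passed.

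**Figure D3:**
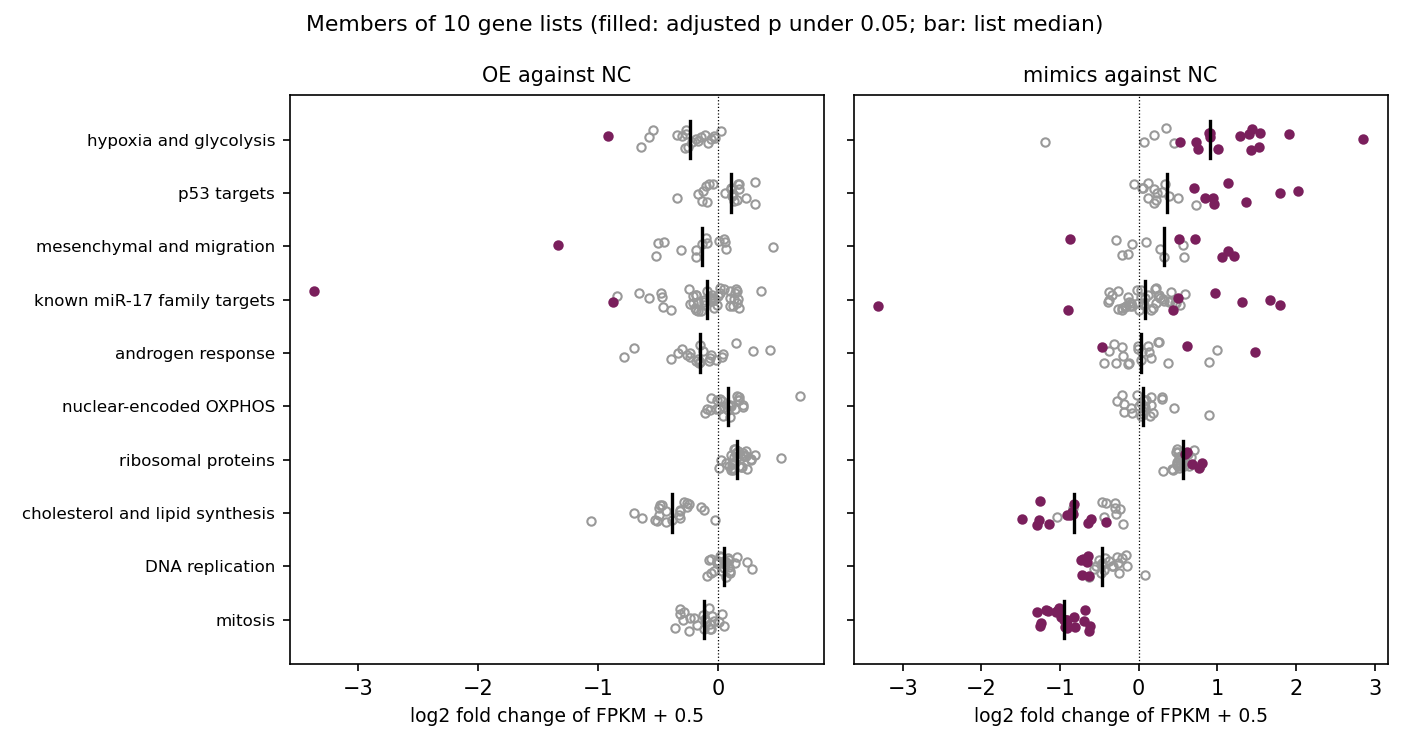
Log2 fold changes of the members of 10 gene lists in OE against NC and in mimics against NC, 1 point per gene, filled where the adjusted p is under 0.05, with a bar at the median. All 22 mitosis genes and 13 of 23 cholesterol synthesis genes were lower and 15 of 20 hypoxia and glycolysis genes higher in mimics.

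Of 30 ribosomal protein genes 5 rose, among them RPS23, antisense to ATG10 (0.81, adjusted p = 0.0280), RPL5, antisense to DIPK1A (701 ± 41.6 to 1200 ± 208 FPKM, 0.76, adjusted p = 0.0280) and RPS19 (0.67, adjusted p = 0.0212), and 29 were higher when adjusted over the list alone. The list had a median of 0.56 (adjusted p = 0.0844, and 0.477 with an estimated correlation), and 3 to 15 members rose over the 5 scalings. It passed after quantile normalization (0.0108, in a range of 0.0108 to 0.265). The 9 listed mitochondrially encoded genes had a median of -2.21 with none past the threshold (limma; 7 lower when adjusted over the list alone, fry adjusted p = 0.365, and 0.509 with an estimated correlation), such as MT-CO1 at 8578 ± 107 FPKM in NC and 3215 ± 4059 in mimics. All 13 such rows lay lower in mimics replicate 2 than the NC mean, with a median of -4.001 on the log2 scale (-4.64 to -2.64), against -0.39 in mimics replicate 1. With a single mimics library the list passed, at 0.00208 without mimics replicate 1 and 0.0356 without mimics replicate 2 (range over all settings 0.00208 to 0.596). The 24 nuclear genes of oxidative phosphorylation had a median of 0.06, and none passed by limma (fry adjusted p = 0.462; ATP5F1A 0.90, adjusted p = 0.113, and UQCRB 0.45, 0.0882).

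Among 49 known targets of the miR-17 family 6 rose and 2 fell, over all rows and when adjusted over the list alone (median 0.09, fry adjusted p = 0.149). CDKN1A, the kinase MKNK2 (48.2 ± 1.54 to 156 ± 34.6 FPKM, 1.66, adjusted p = 0.000881), RAB31, DUSP2 (0.97), TXNIP (0.50) and BTG3 (0.44) rose, and EPHA4 and the mitotic kinesin KIF23 (-0.89) fell. ER stress and amino acid genes had 5 lower of 22, namely the serine synthesis enzymes PHGDH (-0.79, adjusted p = 0.0387) and PSAT1 (-0.48) and the ER proteins PDIA4 (-0.58, 0.0171), HSPA5 (-0.57) and SDF2L1 (-0.52), and 1 higher, the mTORC1 inhibitor DDIT4 (33.7 ± 4.30 to 123 ± 22.7 FPKM, 1.85, 0.000530). That list did not pass (median -0.28, adjusted p = 0.243, with 2 higher and 9 lower when adjusted over the list alone). Immediate early genes had 2 higher, DUSP1 (0.88, adjusted p = 0.00420) and KLF4 (0.61), and 2 lower, EGR3 and FOSB (-0.75, 0.0446), of 21, with a median of 0.14 and a mean of -0.09 (adjusted p = 0.529).

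Androgen response genes had 2 higher, NDRG1 (32.3 ± 4.14 to 90.7 ± 5.75 FPKM, 1.48, adjusted p = 0.000530) and ELL2 (0.61, 0.0220), and 1 lower, the condensin subunit NCAPD3, antisense to JAM3 and VPS26B (-0.47, 0.0366), of 23 (median 0.03, adjusted p = 0.466). Of 8 neuroendocrine genes only CHGB, the granule protein chromogranin B, rose (1.21, adjusted p = 0.00396; list median 0.19, adjusted p = 0.146), and of 25 RAB GTPases only RAB31 (list median 0.03, adjusted p = 0.0881). Without mimics replicate 1 the neuroendocrine and androgen lists passed (0.0393 each, in ranges of 0.0393 to 0.322 and 0.0393 to 0.673), and after quantile normalization the RAB GTPases (0.0451, range 0.0451 to 0.450). In the fit to all 6 libraries the adjusted p with an estimated correlation was 0.477 for neuroendocrine genes, 0.789 for androgen response and 0.539 for RAB GTPases. No member passed by limma among 14 interferon response genes (median -0.02 and mean 0.03, adjusted p = 0.607; ISG20 0.51, IFITM3 0.37), 7 NF-kB genes (median 0.14, 0.5001; NFKB1 -0.58, TRAF1 0.37), 13 microRNA machinery genes (-0.10, 0.466; MCM7 -0.63 and DGCR8 -0.42, each antisense to another gene) or 4 histone genes (0.45, 0.496; HIST1H2BK 0.50, HIST1H1C 0.48).

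Markers of other cell types were mostly low. All 4 measured fibroblast markers were higher in mimics when adjusted over the list alone but none over all rows (median 0.68, adjusted p = 0.0881). COL3A1 had a log2 change of 1.13 and COL1A1 of 0.71. The keratan sulphate proteoglycan LUM was 82.1 to 87.4 FPKM in NC and OE and 172 and 103 in mimics. This list passed without mimics replicate 1 (0.0124) and without mimics replicate 2 (0.00438, in a range of 0.00438 to 0.322). In the fit to all 6 libraries it had adjusted p = 0.346 with an estimated correlation. The leukocyte gene CD68 was 1.82 to 2.96 FPKM and PTPRC was listed at 0 to 0.0101. The endothelial gene EGFL7 was 0.849 to 1.604 FPKM in NC and OE and 2.94 and 3.01 in mimics, where it rose (0.76, adjusted p = 0.0277). Basal prostate keratin KRT5 was listed at 0 in all 6 libraries, KRT15 was 0.712 to 1.604 and S100A2 0.224 to 1.18 FPKM.

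In total 1120 rows passed in mimics against NC, 600 higher and 520 lower, with 3615 at an unadjusted p under 0.05 and 238 beyond a change of 1. The libraries did not overlap for any of the 1120, nor for 52.9% of all tested rows against 33.3% by chance. Of the calls 53.6% were higher, but only 33.8% of 1200 calls after rescaling without the mitochondrially encoded genes. Without NC replicate 1 the count was 66, without NC replicate 2 it was 162, without OE replicate 1 it was 599, without OE replicate 2 it was 597 and without mimics replicate 2 it was 3027. It was 347 without a filter on expression, 601 with only the 4 libraries compared and 2131 at an adjusted p under 0.10. Of the 56 named genes that passed, 22, 28, 49, 49, 52 and 56 still passed without NC replicate 1, NC replicate 2, OE replicate 1, OE replicate 2, mimics replicate 1 and mimics replicate 2.

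OE and mimics were also compared directly, since the title places the noncoding RNA and the microRNA in a single axis. The NC libraries entered this comparison only through the shared estimate of the spread. All 22 mitosis genes were higher in OE than in mimics, and 15 of 20 hypoxia and glycolysis genes, 7 of 22 p53 targets and 7 of 15 mesenchymal genes were lower. These lists passed fry, with adjusted p of 0.239 to 0.262 with an estimated correlation. PFKFB4 was 2.84 ± 0.118 FPKM in OE and 23.3 ± 0.809 in mimics (log2 difference -2.83, SE 0.12, adjusted p = 2.59e-05), and was called in opposite directions against NC. AKAP12, a scaffold for protein kinase A, was likewise called lower in OE (-1.05) and higher in mimics (0.79), at 17.1 ± 1.90 FPKM in NC, 7.98 ± 0.449 in OE and 29.8 ± 1.51 in mimics (difference -1.84, adjusted p = 0.000198). ADM (-3.13, adjusted p = 0.000311), BHLHE40 (-2.88, adjusted p = 0.00108) and PDK4 (-2.81, adjusted p = 0.000703) were among the largest differences, as were the readthrough transcripts JMJD7-PLA2G4B (-2.73, adjusted p = 0.0150) and ATP6V1G2-DDX39B.

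Genes higher in OE than in mimics were ALB, serum albumin, at 39.4 ± 0.725 against 16.7 ± 7.61 FPKM (1.29, adjusted p = 0.0177), and a set whose reads may be shared with overlapping genes: NXF2B (2.65, adjusted p = 0.0137), ENSG00000015479 (2.01, adjusted p = 0.0139) and PLA2G4B (1.58, adjusted p = 0.00226). MT-ATP8, which overlaps MT-ATP6, was also higher (2.32, adjusted p = 0.0471), with 1297 FPKM in mimics replicate 1 and 256 in mimics replicate 2, the library with few mitochondrially encoded reads, against 2849 and 2916 in OE. TOMM6, a subunit of the mitochondrial import pore that overlaps AL365205.1 (3.65, adjusted p = 0.0423), was 108 FPKM in NC replicate 1 and 7.90 in NC replicate 2, which makes its level in control cells undefined.

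All 22 mitosis genes were higher in OE than in mimics (adjusted p = 0.0230, and 0.262 with an estimated correlation). Lower in OE were 15 of 20 hypoxia and glycolysis genes (adjusted p = 0.00340, and 0.262 with an estimated correlation), 7 of 22 p53 targets (0.00155, and 0.239 with an estimated correlation) and 7 of 15 mesenchymal and migration genes (0.00337, and 0.254 with an estimated correlation), among them S100A4 (-1.249), ITGA5 (-1.23) and LOX (-1.05). Of 49 known miR-17 family targets 11 were lower in OE, led by MKNK2 (-1.90), RAB31 and CDKN1A (-1.64), and 1, KIF23 (0.78), was higher (adjusted p = 0.0230, and 0.316 with an estimated correlation). Epithelial genes also passed (adjusted p = 0.0463, and 0.345 with an estimated correlation), with CLDN4 (-0.98), KRT19 (-0.83), KRT8 (-0.82, antisense to KRT18), GRHL2 (-0.64) and CLDN7 (-0.49) lower and the junction genes OCLN (0.96) and TJP1 (0.65) higher in OE. Fibroblast markers (COL1A1 of 4 lower), interferon genes (ISG20, IFITM3 and STAT2 of 14 lower) and RAB GTPases (RAB31 of 25 lower) each had adjusted p = 0.04997, and 0.316, 0.345 and 0.548 with an estimated correlation.

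The other 12 lists did not pass, with adjusted p of 0.0546 for NF-kB (0 of 7 by limma), 0.0855 for DNA replication (6 of 25 higher in OE) and for androgen response (1 higher, 2 lower), 0.0979 for ribosomal proteins, 0.108 for immediate early genes (6 of 21 lower), 0.122 for cholesterol synthesis (3 of 23 higher), 0.194 for ER stress (5 higher, 1 lower), 0.252 for mitochondrially encoded genes (median 2.35, 9 higher when adjusted over the list alone) and 0.271 for neuroendocrine genes (ENO2 and CHGB lower, median 0.02 and mean -0.24). MicroRNA machinery, histone and nuclear oxidative phosphorylation lists had 0.392, 0.479 and 0.680. Without NC replicate 1 or NC replicate 2 the hypoxia, mesenchymal and p53 lists alone still passed (0.0154 each), without OE replicate 1 or OE replicate 2 only the mesenchymal (0.0360 and 0.0470) and p53 lists (0.0360 and 0.0373), and without mimics replicate 1 there were 15 list calls. Mitosis then had 0.0813 without NC replicate 1 or NC replicate 2, 0.155 without OE replicate 1 and 0.141 without OE replicate 2. Without mimics replicate 2 there were 10, with epithelial genes (0.0767) and RAB GTPases (0.137) no longer among them, and quantile normalization ended the call of fibroblast markers (0.0687, range 0.00405 to 0.208).

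In OE against mimics 1098 rows passed, 353 higher and 745 lower in OE, with 3704 at an unadjusted p under 0.05. Libraries did not overlap for any of the 1098, nor for 55.7% of all tested rows against 33.3% by chance. The share of calls higher in OE was 32.1%, but 43.3% after quantile normalization and 52.3% after rescaling without the mitochondrially encoded genes. The count was 626 without NC replicate 1 or NC replicate 2, 136 without OE replicate 1, 180 without OE replicate 2 and 2774 without mimics replicate 2. It was 325 without a filter on expression, 641 with only the 4 libraries compared and 2170 at an adjusted p under 0.10. Of the 13 named genes that passed, 7 and 9 still passed without OE replicate 1 and OE replicate 2, and 12 without each of the other 4 libraries.

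The responses to OE and mimics overlapped in the genes that fell. EPHA4, GJA3, RGMA, SPOCK2, MAOA, CRYAB, DKK1, STAT6, ANXA2, AKR1C2, SLC43A3, NPR1, ATP1B1, SLC37A1, COL9A3, MIEF2, LMO4, GSDMD and FLII passed as lower in both, 19 genes against 1.26 expected of independent lists. MIEF2 and FLII are neighbours on opposite strands of chromosome 17, without overlap with each other, but FLII, ATP1B1, SLC37A1 and COL9A3 lie antisense to other genes. The median log2 changes of the 19 genes were -1.46 in OE and -1.36 in mimics. HMOX1 and Z83844.3 were higher in both (2 against 0.0857 expected), and PFKFB4 and AKAP12 were lower in OE and higher in mimics (2 against 1.46).

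Because both comparisons use the same NC libraries, the overlap was set against simulations of unchanged groups. Across 13998 rows the fold changes correlated at r = 0.290 (0.499 simulated) and rho = 0.233 (0.473 simulated), and 57.7% had the same sign (66.6% simulated). The simulated values come from the shared controls alone. Changes in mimics that OE does not share lower all 3 measures, so observed values under the simulated ones do not show agreement below chance. The covariance was 0.0244 against 0.0155 simulated (0.0141 to 0.0171), a difference of 0.00895. It was 0.0408 without NC replicate 1 and 0.0412 without NC replicate 2. A lone control library adds more shared scatter than a mean of 2, and no simulation was run for that case, so these values do not show closer agreement. With NC replicate 1 used for OE and NC replicate 2 for mimics, a choice made after seeing the data, the covariance was 0.0152 (r = 0.160, 52.9% with the same sign). With the 2 exchanged it was 0.000568 (r = 0.00512, 47.7%). Each of these rests on 1 control library per comparison and was not tested. Part of the overlap beyond independent lists may thus come from the shared controls. The count of genes called in both in the same direction, 21, was 3 without NC replicate 1, 5 without NC replicate 2, 5 without OE replicate 1, 4 without OE replicate 2, 57 without mimics replicate 1 and 68 without mimics replicate 2.

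**Figure D4:**
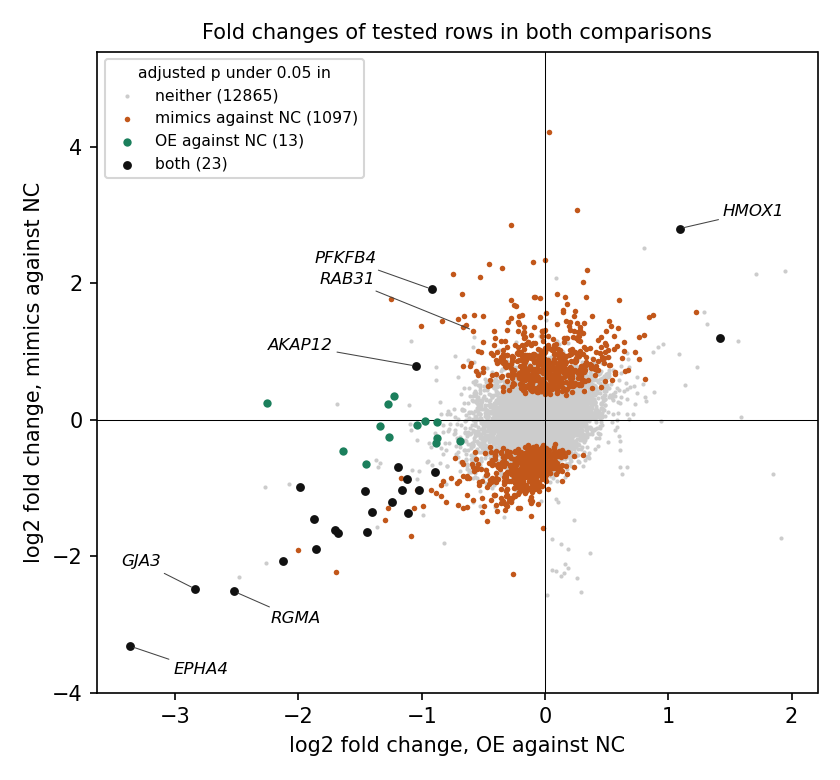
Log2 fold change of each tested row in OE against NC (horizontal) and mimics against NC (vertical), coloured by whether the adjusted p is under 0.05 in neither comparison (12865 rows), mimics only (1097), OE only (13) or both (23). EPHA4, GJA3 and RGMA lie lowest in both, and PFKFB4 and AKAP12 lie lower in OE and higher in mimics.

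A microRNA lowers transcripts with seed matches in their 3′ UTR, so genes with such matches were compared as a set. In mimics against NC the median log2 change was 0.0024 for 3033 genes with GCACTTT and -0.0088 for 6197 genes without the shorter match of 6 bases, a difference of 0.0112. The genes with a match lay at percentile 25.9 of random lists matched on expression and 3′ UTR length (95% of lists between -0.0037 and 0.0146). Without mimics replicate 2, the library with few mitochondrially encoded reads, they lay at percentile 2.36, below the 95% range of matched lists, and at 37.97 without mimics replicate 1, 3.41 without NC replicate 2 and 52.3 without NC replicate 1. For the 650 genes with an 8-base match the percentile was 62.9, with 28 called higher and 13 lower by limma (0.759 by fry, unadjusted). Of genes with a 7-base match 3.17% were called lower and 3.79% higher in mimics, against 4.66% and 4.84% of genes without a match. Among 16232 heptamers this one ranked 7757 from the most negative, and 5212 after removal of trends with 3′ UTR length, GC content and expression.

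In OE against NC the genes with a match lay at percentile 40.7 (difference 0.0346), but at 4.03 without OE replicate 1, 8.13 without NC replicate 2, 82.8 without OE replicate 2 and 86.8 without NC replicate 1. Single libraries thus set this value. In OE against mimics they lay at 64.2 (difference 0.0172), at 25.4 without OE replicate 1, 72.7 without OE replicate 2, 91.1 without mimics replicate 1 and 58.8 without mimics replicate 2. For the 650 genes fry gave an unadjusted 0.635 and 0.429. EPHA4 holds 2 matches in its 3′ UTR of 3343 nucleotides on chromosome 2, an 8-base match with its core at 221425971 to 221425977 and a 7-base match at 221425952 to 221425958.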

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

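The rescaling without mitochondrially encoded genes, the fit of annotated genes only, the fit without genes that share exon sequence and the split of the NC libraries were chosen after seeing the data, and the other settings before the data were examined. No result that passed changed direction under any setting run, while the seed match shift, which did not pass, changed sign with some libraries left out. Of single named genes and lists that passed, 1098 combinations of result and setting kept their call and 110 lost it when no library was left out, while with 1 library left out 370 combinations for genes kept it and 146 lost it, and 44 for lists kept it and 40 lost it. RAB31 kept its calls in mimics against NC and OE against mimics under every setting run, with adjusted p from 0.00200 to 0.0475 and from 0.000267 to 0.0221. The 3 added fits gave 36, 40 and 32 genes called for OE against NC, 1200, 1246 and 914 for mimics against NC and 1066, 1233 and 928 for OE against mimics. The implied depth is only approximate and may be too low, and counting error was not compared with the spread of the 2 libraries per group.

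Without a filter the genes called numbered 0 in OE against NC by limma (1334 at an unadjusted p under 0.05; the other limma settings without a library left out gave 9 to 119), 347 in mimics against NC and 325 in OE against mimics, where more rows near zero entered the trend and the adjustment. With only the 4 libraries compared they numbered 119, 601 and 641, with fewer residual degrees of freedom and without the spread of the third group. The spread was unequal: the mimics libraries differed from each other by a median absolute log2 value of 0.202, against 0.131 for NC and 0.105 for OE. The shared estimate thus takes mimics scatter into OE against NC and the smaller NC and OE scatter into mimics against NC. How far this set the counts was not tested. An adjusted p under 0.10 gave 2131 genes called in mimics against NC and 2170 in OE against mimics. A filter of 2 FPKM gave 1 list called in OE against NC and 13 genes called in both in the same direction, and quantile normalization 1 list called in OE against NC, and the cause was not tested. Leaving out 1 library gave 5 to 120 genes called in OE against NC, 66 to 3027 in mimics against NC and 136 to 2774 in OE against mimics. The lone library left in a group is then assumed to vary like the others. Lists called ranged from 1 to 9 in mimics against NC and 2 to 15 in OE against mimics, genes called in both in the same direction from 3 to 68, and the covariance of fold changes from 0.0215 without OE replicate 2 to 0.0408 without NC replicate 1 and 0.0412 without NC replicate 2. A lone control library shared by both comparisons adds more scatter to the covariance than a mean of 2. With the NC libraries split the covariance was 0.0152 with number 1 for OE and 0.000568 with number 2 for OE, where no control library is shared. The miR-106a-5p seed match shift in mimics against NC was 0.0191 without mimics replicate 2 (percentile 2.36) and from -0.0273 to 0.0544 over the libraries left out.

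The replicate numbers were not taken as pairs in the main fit. Deviations of same-numbered libraries correlated across genes at 0.153 for NC and OE, -0.0268 for NC and mimics and 0.0194 for OE and mimics. A weak link between same-numbered NC and OE libraries thus stays open. With the replicate number as a block, 9 genes were called in OE against NC, 938 in mimics against NC and 938 in OE against mimics, and 6 in both in the same direction. Lists called with the block were 2 in OE against NC (epithelial genes and miR-17 family targets, 0.0444 each), 1 in mimics against NC (p53 targets, 0.00831) and 5 in OE against mimics. In the fit without a block the 2 lists in OE against NC each had adjusted p = 0.308 by camera with an estimated correlation.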

Other observations

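The metallothioneins and the oxidative stress genes described here were chosen only after their values were seen, as were the tests on scaling, on exchanged labels, on genes without a 6-base seed match or with that match alone, on the control cells, on the mimics library with few mitochondrial reads and on culture conditions, whereas the simulation of shared controls and the Fisher test were chosen before. Metallothioneins, small proteins that bind zinc and copper, rose in mimics against NC: MT1G by 2.34 (adjusted p = 0.00132), MT1X by 2.23 (0.000206), MT2A by 1.36 (0.0139) and MT1E by 0.99 (0.0182) on the log2 scale, each with both mimics libraries above both NC libraries. All 4 rose under each of the 5 scalings, from 0.90 to 2.40. In OE against NC 0 of 4 were called by limma under any of these scalings, with adjusted p of 0.640 to 0.9996, and each was lower in OE than in mimics (8.52e-05 to 0.00396).

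Of 24 tested genes of the NRF2 oxidative stress response, which handle heme, iron and thiols, 9 rose and 2 fell in mimics, and the others did not pass. Those that rose included NQO1, a quinone reductase (41.5 to 99.0 FPKM, 1.23, adjusted p = 0.00223), and the ferritin chains FTH1, antisense to BEST1 (713 to 1535 FPKM, 1.09, 0.00980) and FTL (329 to 592 FPKM, 0.85, 0.00758), while AKR1C2 (-1.04, 0.0122) and PGD (-0.56, 0.0154) fell. Over the 5 scalings 6 to 9 rose and 2 or 3 fell. In OE only HMOX1 rose and only AKR1C2 fell, with NQO1 at 0.56 (0.273) and GCLM at 0.54 (0.265) not passing. The unadjusted fry p was 0.00251 in mimics and 0.0323 in OE, or 0.00888 and 0.0973 for the 20 members not named elsewhere in the text. Since the members were picked with their values in view, these p-values are not independent evidence of a response.

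RAB31 was higher in mimics than in NC although its 3′ UTR holds a miR-106a-5p seed match, and genes with such a match were not lower as a set. Scaling is argued against, because the RAB31 log2 change was at least 1.23 under each of the 5 scalings. An exchange of the OE and mimics labels stays open: genes with a match lay at percentile 40.65 of matched random lists in OE against NC, but at 4.03 without OE replicate 1 and 86.8 without NC replicate 1, which decides nothing, and MAGI2-AS3, which would decide, was not analysed here. Without mimics replicate 2 the genes with a match lay at percentile 2.36 in mimics against NC. The value also moved with the controls, at 3.41 without NC replicate 2 and 52.3 without NC replicate 1. In OE against mimics, where repression in mimics would raise the percentile, it was 58.8 without mimics replicate 2 and 91.1 without mimics replicate 1. Whether mimics replicate 2 hides a weak repression is therefore not decided.

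The 19 genes that fell in both OE and mimics had almost equal falls, with a median absolute difference of 0.13 between the groups. Some lay under the pseudocount of 0.5 FPKM in both, such as RGMA (0.126 and 0.128) and DKK1 (0.0649 and 0.0524), where this scale hides differences. Others lay well above it, such as ATP1B1 (difference -0.04) and FLII (-0.13). Whether chance scatter of the shared NC libraries adds to these genes stays open. At most 2 such genes were called in 100 simulations of unchanged groups. With every group unchanged, few rows pass the adjustment, so the simulated count was bound to be low. In the data 1120 rows passed in mimics against NC. The simulations also cover only independent scatter and not a shift common to both NC libraries. Direct repression through a 3′ UTR seed match is argued against for 7 of the 19, which had no 6-base match in any annotated 3′ UTR. For the others, 1 of which had such a match outside the longest 3′ UTR only, it stays open: a 7-base match was held by 4 (EPHA4, GJA3, RGMA and MIEF2), 21.1% against 24.8% of tested genes (one-sided Fisher exact p = 0.731), where the bound set beforehand, a share at or under that of tested genes, was not enough because the exact interval reaches from 6.05% to 45.6%, and 7 held only a 6-base match, 36.8% against 24.4% (16.3% to 61.6%, one-sided Fisher exact p = 0.160). That the NC cells differed from both other cultures may also explain the falls and cannot be told apart, as no other control group was measured. Only 1 of the 19, MAOA, differed between OE and mimics (limma adjusted p = 0.0134). This decides nothing, because the 19 were chosen as lower in both, which favours genes with like levels in the 2 groups.

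Mitosis genes were lower and hypoxia genes higher in mimics. Scaling is argued against, as at least 14 of 20 hypoxia and glycolysis genes rose under each of the 5 scalings, and so is an effect of the library with few mitochondrial reads alone, as all 22 mitosis genes lay under both NC libraries in mimics replicate 1 too. Density, medium or handling of the mimics cultures cannot be told apart from the microRNA, since 19 of 20 hypoxia genes lay above both NC libraries in mimics replicate 2 as well and no second control culture exists among the libraries used here. A response to the microRNA itself may therefore be involved but was not separated from these.

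TOMM6 was 108 and 7.90 FPKM in the NC libraries, 112 and 114 in OE and 9.22 and 7.98 in mimics. GAPDH was 528 and 1717 FPKM in the mimics libraries, against 2021 to 2341 in NC and OE. ATP5F1A was 484 and 213 FPKM in the NC libraries. KLK4 was 141 and 344 FPKM in the mimics libraries. RPL23 was 238 and 511 FPKM in the OE libraries.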
